A study of Mus musculus with 9 samples.

How the data were processed

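RNA recovered with Argonaute 2 (Ago2), the protein that carries microRNAs and holds their target transcripts, was measured in amygdala of male C57BL/6J mice that were 10 weeks old when chronic social defeat began. Chronic social defeat is a stress protocol in which a mouse is repeatedly exposed to an aggressor. Tissue was taken 8 days after the end of defeat, Ago2 was immunoprecipitated, and 100 ng of RNA was labelled for an Affymetrix whole-transcript array, per the labels' protocols. There were 9 arrays in 3 groups, with 3 control arrays (numbered 1, 2 and 4), 3 susceptible and 3 resilient arrays. The sample titles gave the groups, and the criterion that separated susceptible from resilient mice is not given in the sources used here. The labels do not say whether each array came from a separate animal, so p-values measure only the spread between these samples, which may be technical.

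The deposited values were on the log2 scale and came from RMA (background correction, quantile normalisation and summary of probes per transcript), with Partek also named, per the submitters' processing notes. Array type version, annotation build and software versions are not given in the sources used here. Array medians lay between 7.11 and 7.19. RMA's summary step gives exact ties, and 5948 of the 11772 table entries had at least 2 arrays at one value. The gene symbols were taken from a second deposited table, joined by probe set identifier. That table also held 9 value columns whose names matched no sample label, and these were not used.

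The deposited table was selected on the outcome. For every symbol, the smallest p of a one-way analysis of variance over the 3 groups, computed from the deposited values, was at most 0.287, and the symbol table was sorted by this p (Spearman's rho 1.00 across entries). The entries with a larger p, 974 in number, all belonged to symbols that had another entry below it. Among the 8825 symbols with 1 entry, values of this p were spread almost evenly, with 991 in the lowest of 10 equal parts of that range and 776 in the highest, against 882.5 for an even spread. Genes that differed little between groups are therefore missing, and adjusted p-values over the table are smaller than they would be over all genes of the array. An alternative divided each p by 0.287 before adjustment, which allows for the missing genes. Shares of genes that rose or fell, list sizes and gene list tests also refer to this selected table. If this p were spread evenly, the table would stem from about 34215 symbols. Counts at an unadjusted p under 0.05 therefore hold chance differences from that larger number and are not numbers of changed genes.

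For each of 9803 symbols the entry with the highest mean over the 9 arrays was kept, since 978 symbols had several entries. Symbols were updated through an NCBI gene table (assembly GRCm38.p6), in which 8393 were current, 1012 were replaced by a newer symbol, 10 were kept because the newer symbol was already present and 388 had no match and kept the deposited name. No genome or transcript sequence was used, so positions are not given.

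One limma model with a mean per group was fitted to all 9 arrays (lmFit, contrasts.fit and eBayes, two-sided, no filter on low values). Benjamini-Hochberg adjustment ran over the 9803 genes of each comparison, and a gene was called at an adjusted p under 0.05. The 4 comparisons were defeated (mean of the susceptible and resilient groups) minus control, susceptible minus control, resilient minus control, and susceptible minus resilient. The eBayes prior had 3.40 degrees of freedom. R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. Errors of differences are limma's standard errors (SE), and errors of group means are standard deviations (SD).

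There were 37 gene lists, of which 32 had at least 5 members in the table and were tested with camera at a preset correlation of 0.01, adjusted over all 128 tests. Camera with an estimated correlation and fry were alternatives. Each list's median was also ranked among 10000 random lists matched on signal and gene length, as a description. The lists were immediate early genes, glucocorticoid-induced genes, steroid receptor chaperones, the CRH, steroid and stress peptide system, microRNA machinery, reported miR-15/16 family targets, potassium channels, glutamate receptors, the dopamine and opioid systems, synaptic plasticity genes, protocadherins, zinc finger proteins, inflammatory genes, interferon-stimulated genes, circadian clock genes, chromatin regulators, histone genes, cytosolic ribosomal proteins, the mitochondrial respiratory chain, microRNA genes, small nucleolar RNA genes, and olfactory and vomeronasal receptors. Marker lists covered central amygdala and striatal-type neurons, basolateral amygdala and cortical excitatory neurons, thalamus and hypothalamus, pan-neuronal genes, astrocytes, oligodendrocytes and myelin, microglia and macrophages, endothelial and mural cells, choroid plexus and ependyma, and blood cells. The GABA, serotonin and endocannabinoid systems, hippocampal markers and oligodendrocyte precursor markers had too few members for a test.

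Genes were named by a rule. In each comparison and direction these were the 10 genes with the largest difference among those called. Where fewer than 10 were called, the list was filled to 10 with the genes of lowest unadjusted p whose mean signal was above the median of all genes, given as values only. Predicted genes, unstudied genes and chemosensory receptors were counted but not named. Also named were 13 genes of the stress and microRNA systems (Fkbp5, Nr3c1, Nr3c2, Crh, Crhr1, Ago2, Dicer1, Bdnf, Fos, Slc6a4, Htr1a, Mir15a and Mir16-1) and the 3 members of lowest p of each called list. Other members are given as examples of a list's values. A few genes that the rule names are not reported here. Of the 13 genes, 5 were in the table. Adjusted limma p-values over the 13 genes gave each absent gene the largest possible value, so the adjustment does not count the other genes kept, although the variance prior of limma was estimated from them.

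The groups, comparisons, gene lists, naming rule and most alternatives were fixed before the data were examined. The alternatives tried were every table entry tested, 2 filters on low signal, arrays shifted to one median, quantile normalisation, eBayes with trend and robust, no moderation, array weights, only the groups compared, the replicate number as a block, a call at unadjusted p under 0.05 with at least a 1.5-fold difference, and each array left out in turn. The allowance for selection, choroid plexus content as a covariate, and leaving out 2 arrays together were chosen after seeing the data. Array values correlated across genes at 0.997 to 0.999 within groups and 0.995 to 0.999 between groups, and no arrays were identical.

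The limma step was tested on simulated data with the same selection, for defeated minus control. Among 10052 simulated genes kept, 64.0% of genes with a log2 change of 0.3 were called, 90.0% of those with 0.5, and 100.0% of those with 1 or 2. Selection led to 64 calls among unchanged genes, against 12 with the allowance, where 200 changed genes had been simulated. In 20 simulations with no changed gene and the same selection, the median was 0 calls in each comparison, and the most was 2 for defeated minus control, 1 for susceptible minus control, 5 for resilient minus control and 4 for susceptible minus resilient. Genes were simulated as independent, so these counts set no bound on calls from variation that genes share. A test of microRNA seed matches was not run because no 3' untranslated sequences were used here. The second value table could not serve as an alternative because its columns carried no sample label.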

Results

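Chronic social defeat separates inbred mice into susceptible animals and animals called resilient, and this design asked which transcripts recovered with Ago2 from the amygdala differed 8 days after defeat, and whether the defeated groups differed from each other. The values were log2 RMA signals from 9 whole-transcript arrays, 3 from undefeated controls, 3 from susceptible and 3 from resilient mice. A value can reflect how much of a transcript was present, how much of it was bound to Ago2 and how much was carried over without binding. Total RNA of the same tissue was not analysed here, and none of the 9 arrays was of a control precipitation, so these parts cannot be told apart. The number of arrays limits the precision. The table of 9803 genes had been selected by the authors for a difference between the 3 groups, so a count of genes past an adjusted p of 0.05 is given both as limma gave it and with an allowance for the genes missing from the table.

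Defeated mice had a higher Fkbp5 signal in RNA recovered with Ago2 than controls. Fkbp5 encodes a co-chaperone that lowers the hormone affinity of the glucocorticoid receptor and is itself induced by glucocorticoids. Its log2 signal was 8.31 ± 0.03 in controls (SD, n = 3), 8.74 ± 0.09 in susceptible and 8.65 ± 0.12 in resilient mice (SD, n = 3 each), and all 6 defeated arrays lay above all controls. The difference between defeated and control mice was 0.38 (SE 0.058), or 1.30-fold. Tnrc18, which encodes a large nuclear protein that binds chromatin, rose by 0.37 (SE 0.036), from 8.92 ± 0.03 in controls to 9.37 ± 0.03 in susceptible and 9.22 ± 0.06 in resilient mice (SD, n = 3 each).

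The adjusted p from limma was 0.0371 for Fkbp5 and 0.0187 for Tnrc18, the smallest of the comparison, and 0.130 and 0.0651 with the allowance for selection. Fkbp5 was among the 13 genes fixed in advance, and over those its adjusted p was 0.00103, or 0.00358 with the allowance. The adjusted p of Fkbp5 over all genes was 0.0579 to 0.106 without any one of the controls, susceptible 2, susceptible 3, resilient 2 or resilient 3. In an exact permutation test the p for Fkbp5 was 0.0119, the smallest that 84 arrangements can give. The table was selected with the real groups, which favours the real arrangement in this and the other exact tests given here, and no allowance was made in them. Dicer1, the enzyme that cuts microRNA precursors, was higher by 0.22 (SE 0.056), with an adjusted p of 0.0200 over the fixed genes and 0.0697 with the allowance. Ago2 itself (0.15, SE 0.058), the microRNA precursor Mir15a (0.13, SE 0.065) and the growth factor gene Bdnf (-0.07, SE 0.044) had limma adjusted p-values of 0.106, 0.232 and 0.443 over the same genes.

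limma called 126 genes between defeated and control mice, 99 higher and 27 lower, with a median difference of 1.19-fold. Of these, 56 differed by at least 1.2-fold. Besides Fkbp5 and Tnrc18, the largest increases among the called genes open to naming were those of Pdzd2 (0.39, SE 0.072), the phospholipid flippase Atp11a (0.35, SE 0.054), the collagen receptor Ddr2 (0.35, SE 0.064), the lysosomal thiol reductase Ifi30 (0.35, SE 0.045), the cytoskeletal linker Plec (0.33, SE 0.049), the matrix peroxidase Pxdn (0.33, SE 0.059), Tspoap1, which encodes a presynaptic scaffold protein (0.32, SE 0.058), and the zinc finger gene Zfp516 (0.32, SE 0.051). The largest decreases among those genes were those of the butyrophilin-like pseudogene Btnl5-ps (-0.67, SE 0.12), Filip1l (-0.36, SE 0.056), the GTPase-activating protein gene Arhgap5 (-0.27, SE 0.037), Fam163a (-0.26, SE 0.036), Ms4a15 (-0.26, SE 0.047), Msgn1 (-0.25, SE 0.050), the fatty acid elongation enzyme Hacd2 (-0.24, SE 0.043), Fbxo4 (-0.22, SE 0.042), Sec16b (-0.22, SE 0.041) and Klk10 (-0.20, SE 0.037). A second table entry of Hacd2, at a mean log2 signal of 9.96, had a difference of 0.02, and one of Btnl5-ps, at 4.71, had -0.04. By the entries kept, every one of these 20 genes had all 6 defeated arrays on the same side of all controls. Choosing called genes by their difference on these same arrays favours such a separation, so it is no added support. With the allowance for selection limma called 0 genes, and 3618 had an unadjusted p under 0.05, 2281 of them higher. The direction of the count rested on the scaling, since arrays shifted to one median gave 164 calls of which 42 were higher and 122 lower, and quantile normalisation gave 3, with 1 higher and 2 lower. The count was 0 without control 1, control 2, susceptible 2, susceptible 3, resilient 2 or resilient 3, 9 without control 4, 1333 without susceptible 1 and 430 without resilient 1. Other settings moved it between 0, with the replicate number as a block or choroid plexus content as a covariate, and 2084, with array weights.

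**Figure D1:**
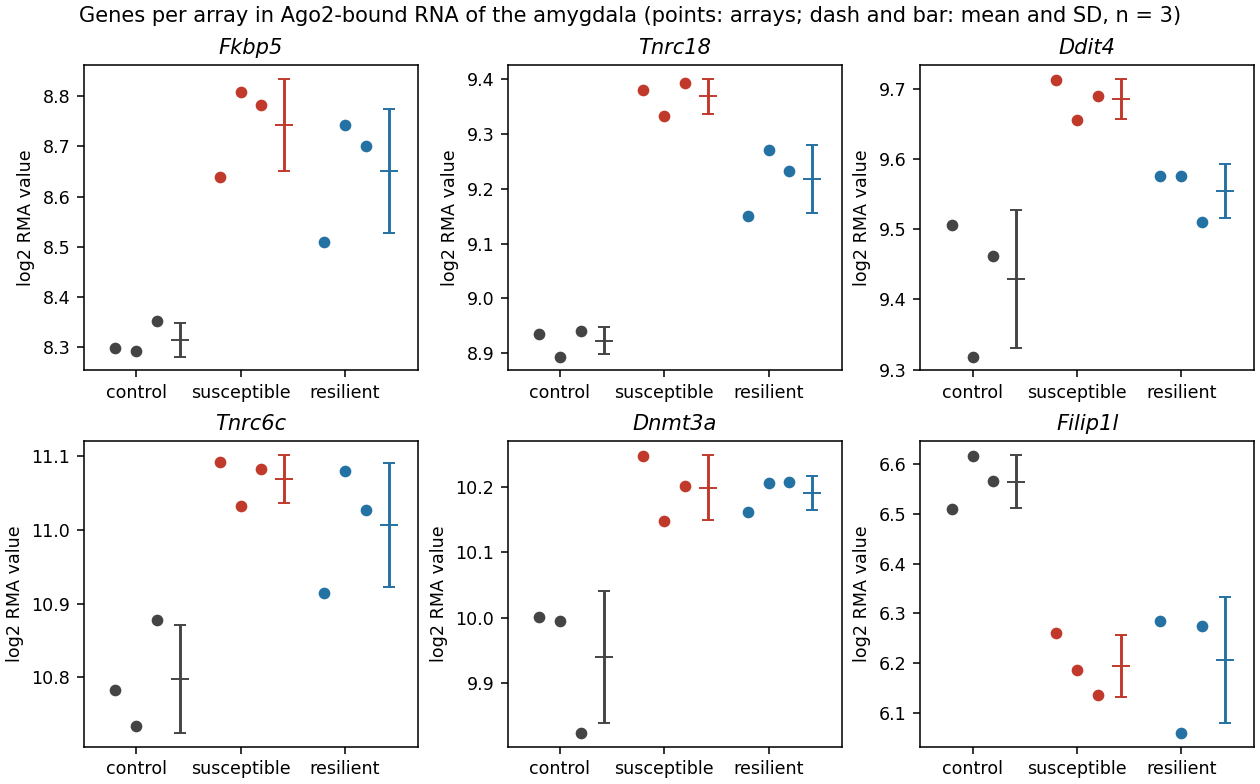
Log2 RMA value of 6 genes on each of the 9 arrays, by group, with points for arrays and a dash and bar for the mean and SD of 3 arrays; each panel has its own axis. All 6 defeated arrays lay above the controls for Fkbp5, Tnrc18, Ddit4, Tnrc6c and Dnmt3a and below them for Filip1l.

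Glucocorticoid-induced genes were higher in defeated mice as a group. Of the 15 members measured, 12 were higher and 3 lower, with a median of 0.14, and the list rose by camera (adjusted p = 0.0468; adjusted p = 0.652 with an estimated correlation). Member counts and medians of lists are to be read beside those of all 9803 genes. Of these, 58.6% were higher in defeated, 57.9% in susceptible and 58.4% in resilient mice than in controls, with medians of 0.04, 0.05 and 0.03. In susceptible minus resilient 54.1% were higher, with a median of 0.01. Counts of members called when adjusted over a list alone, here and below, make no allowance for the table's selection. Among all 9803 genes, 3618 had an unadjusted p under 0.05 in defeated, 3991 in susceptible and 2077 in resilient mice against controls. Such counts are therefore not support for a list. Of the glucocorticoid-induced genes, Fkbp5 was the only one called over all genes, and 8 were called when adjusted over the list alone. Among the other members the mTOR inhibitor Ddit4 had a difference of 0.19 (SE 0.044), the lipid droplet gene Plin4 0.41 (SE 0.13), Tsc22d3 0.22 and Sgk1 0.10. The list's median was 0.09 with arrays shifted to one median. The list's adjusted p was 0.0509 to 0.0801 without control 1, control 4, susceptible 2, resilient 1 or resilient 3, each left out in turn.

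The machinery that loads and uses microRNAs rose as well, with 13 of 15 measured members higher and a median of 0.11 (camera adjusted p = 0.0271; adjusted p = 0.652 with an estimated correlation). Tnrc6c, which encodes an Ago2-binding scaffold of the silencing complex, rose by 0.24 (SE 0.046) and was the 1 member called over all genes, against 8 adjusted over the list alone. The helicase gene Mov10 had a difference of 0.25 (SE 0.063), Tnrc6a 0.17 and Ago1 0.12. Without control 1 or susceptible 1 the list's adjusted p was 0.0693 or 0.0575. Chromatin regulators also rose, with 13 of 14 higher and a median of 0.13 (camera adjusted p = 0.0112; adjusted p = 0.652 with an estimated correlation). The DNA methyltransferase Dnmt3a rose by 0.25 (SE 0.046) and the histone methyltransferase Kmt2a by 0.20 (SE 0.036), which were the 2 members called over all genes, against 6 adjusted over the list alone. Ehmt1, another histone methyltransferase, had a difference of 0.27 (SE 0.062). With arrays shifted to one median the median was 0.06 for the microRNA machinery and 0.09 for chromatin regulators, and with quantile normalisation it was 0.08 and 0.05.

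Markers of oligodendrocytes and of microglia were lower in defeated mice. All 6 oligodendrocyte and myelin genes measured had lower values, with a median of -0.21 (camera adjusted p = 0.0151; adjusted p = 0.652 with an estimated correlation). Differences were -0.47 (SE 0.16) for the myelin protein gene Opalin, -0.29 (SE 0.077) for Aspa, which degrades N-acetylaspartate, and -0.22 (SE 0.087) for the lipid hydroxylase Fa2h, with 0 members called over all genes and 2 adjusted over the list alone. The list average of resilient 1 was 0.08 above the control mean, while the other 5 defeated arrays lay between -0.32 and -0.29. All 8 microglia and macrophage genes were lower, with a median of -0.14 (camera adjusted p = 0.0179; adjusted p = 0.652 with an estimated correlation), among them the complement gene C1qc (-0.19, SE 0.062), the receptor subunit Fcer1g (-0.28, SE 0.11) and P2ry13 (-0.14, SE 0.063). No microglial member was called, either over all genes or adjusted over the list alone, by limma, and the list's camera adjusted p was 0.0985 without control 1, with a median of -0.09, and 0.0555 without susceptible 1. Cytosolic ribosomal protein genes had 10 of 11 members lower and a median of -0.07 (camera adjusted p = 0.0467; adjusted p = 0.675 with an estimated correlation), with Rpl10l at -0.15 (SE 0.049) and Rps6 at -0.07 (SE 0.037). That call ended without any one array except control 2 and resilient 1, with adjusted p between 0.05003 and 0.108, and the median was -0.05 without control 1 and -0.03 without resilient 3. As deposited it stood at percentile 20.2 of random lists matched on signal and gene length. Rpl10l is a testis-expressed paralogue, at a log2 signal of 4.78 in controls. Olfactory and vomeronasal receptor genes, which serve chemosensation in the nose, rose, with 456 of 588 higher and a median of 0.09 (camera adjusted p = 0.00998; adjusted p = 0.717 with an estimated correlation). Among them 3 were called over all genes, all 3 higher, and 0 adjusted over the list alone. With arrays shifted to one median the median was -0.12 for ribosomal proteins and 0.04 for the receptors, and with quantile normalisation it was -0.22 for microglia markers. In exact permutation tests of the list averages, adjusted over the 32 lists, none of the 7 lists passed. The adjusted p was 0.0544 for glucocorticoid-induced genes, the microRNA machinery and chromatin regulators, each at the smallest exact p that 84 arrangements can give. It was 0.114 for olfactory and vomeronasal receptors, 0.139 for oligodendrocyte markers, 0.152 for microglia markers and 0.346 for ribosomal proteins in the same exact tests. Synaptic plasticity, interferon-stimulated and circadian clock genes and zinc finger proteins, which camera did not call in defeated mice, also had 0.0544. All lists with 0.0544 were at the smallest exact p, so their adjusted p was fixed by how many lists were there. With choroid plexus content as a covariate the camera adjusted p in defeated mice was 0.0137 for glucocorticoid-induced genes and 0.00265 for chromatin regulators, and 0.0940 for the microRNA machinery, 0.131 for oligodendrocyte markers, 0.137 for microglia markers, 0.445 for ribosomal proteins and 0.113 for olfactory and vomeronasal receptors. The choroid plexus and ependymal markers themselves had a median of 0.32 between defeated and control mice (camera adjusted p = 0.0770).

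**Figure D2:**
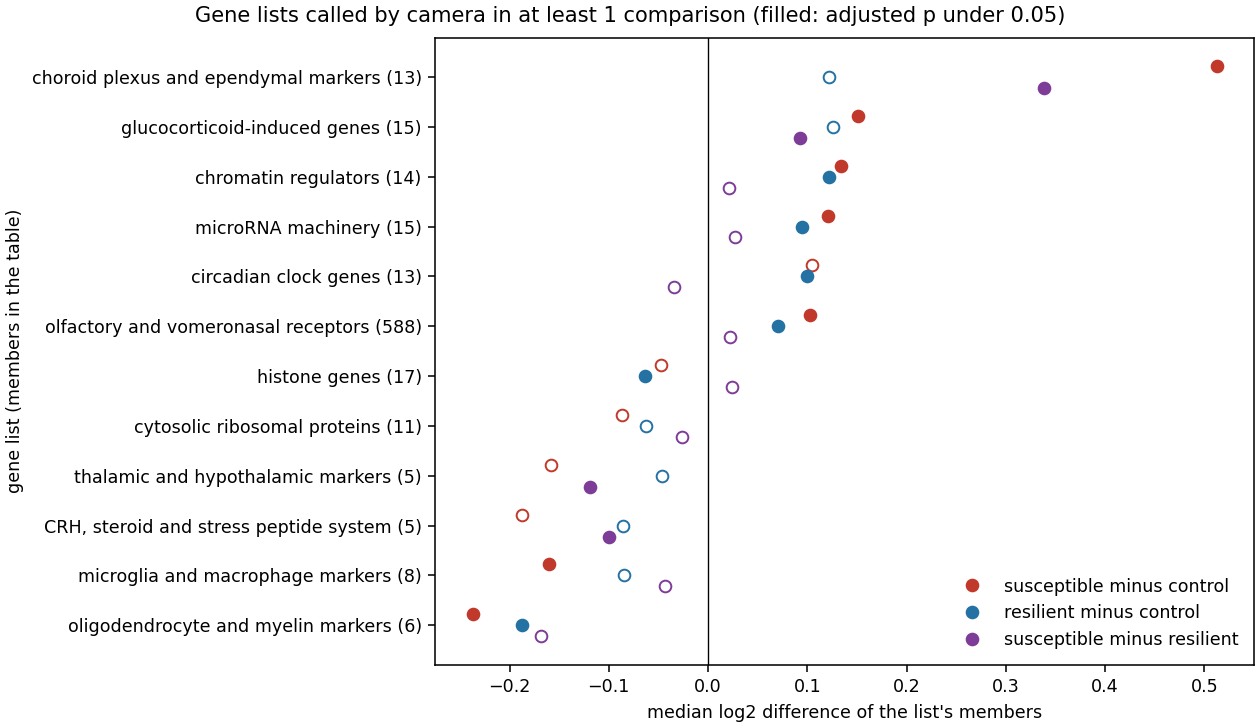
Median log2 difference of each gene list called in at least 1 comparison, with the number of measured members in parentheses; filled circles mark an adjusted p under 0.05 by camera with its preset correlation, and ribosomal proteins were called only between all defeated mice and controls, which is not drawn. Choroid plexus markers had the largest median, 0.51 in susceptible minus control, and oligodendrocyte markers the lowest, -0.24.

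In susceptible mice set against controls, A2m, which encodes a protease inhibitor of plasma, had the largest increase among called genes. Its log2 signal was 7.92 ± 0.04 in controls and 8.69 ± 0.12 in susceptible mice (SD, n = 3 each), a difference of 0.78 (SE 0.15) or 1.71-fold. The transporter gene Abca4, not called and chosen after its values were seen, differed by 0.78 (SE 0.29, limma adjusted p = 0.0968). The developmental receptor gene Notch2 rose by 0.58 (SE 0.13), the alcohol dehydrogenase gene Adh1 by 0.50 (SE 0.083), Wfikkn2, which encodes a secreted inhibitor of growth differentiation factors, by 0.49 (SE 0.10) and Tnrc18 by 0.45 (SE 0.041). Fkbp5 rose by 0.43 (SE 0.067), or 1.35-fold. Ifi30 rose by 0.42 (SE 0.052), the cell cycle gene Ccnd3 by 0.42 (SE 0.086), the transcription factor gene Usf1 by 0.41 (SE 0.080) and Pxdn by 0.40 (SE 0.068).

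The largest decreases in susceptible mice among the called genes open to naming were those of Btnl5-ps (-0.72, SE 0.14), the microRNA gene Mir194-1 (-0.47, SE 0.093), Cd180, which encodes a Toll-like receptor homologue of B cells and myeloid cells (-0.47, SE 0.079), and the T cell receptor segment Trav13d-4 (-0.41, SE 0.084). Filip1l fell by 0.37 (SE 0.064). Also lower were the microRNA genes Mir351 (-0.36, SE 0.067) and Mir449a (-0.32, SE 0.056), the GPI anchor synthesis gene Pigp (-0.31, SE 0.064), Msgn1 (-0.29, SE 0.058) and Ms4a15 (-0.29, SE 0.054). Of the 149 microRNA genes in the table, only 32 had a control signal above the 95th percentile of olfactory and vomeronasal receptors. Larger differences that limma did not call, chosen after their values were seen, were -1.04 for Scn4b, -0.89 for Slc18a3 and -0.86 for Slc5a7. The adjusted limma p was 0.0130 for Tnrc18 and 0.0397 for Fkbp5. Over the genes fixed in advance it was 0.00130 for Fkbp5, or 0.00455 with the allowance for selection, and 0.0584 for Dicer1 and 0.0942 for Ago2. The exact permutation p for Fkbp5 was 0.100, the smallest that 3 arrays against 3 can give.

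limma called 235 genes in this comparison, 181 higher and 54 lower, with a median difference of 1.22-fold, and 151 differed by at least 1.2-fold. With the allowance for selection 1 gene, Tnrc18, remained (adjusted p = 0.0454), and 3991 had an unadjusted p under 0.05. Of the 235, 112 were also called between all defeated mice and controls, a comparison that uses the same susceptible and control arrays. Arrays shifted to one median gave 1497 calls, 231 higher and 1266 lower, and quantile normalisation gave 12, 5 higher and 7 lower. The count was 0 without control 1, control 2, susceptible 2 or susceptible 3, 1 without resilient 2, 89 without control 4, 136 without resilient 3, 386 without resilient 1 and 1930 without susceptible 1. It was 0 without susceptible 3 and resilient 1 together and with the replicate number as a block, and 3443 with array weights.

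Choroid plexus and ependymal markers had the largest shift of any list in susceptible mice. All 13 measured members were higher than in controls, with a median of 0.51 (camera adjusted p = 0.0171; adjusted p = 0.675 with an estimated correlation). Differences were 0.73 (SE 0.27) for the bicarbonate transporter Slc4a5, 0.55 (SE 0.20) for the folate receptor Folr1, 0.53 (SE 0.19) for Kl, which encodes klotho, and 0.51 (SE 0.14) for Clic6, and limma called 0 members, over all genes or adjusted over the list alone. The transcript of transthyretin, Ttr, the most abundant product of choroid plexus, was at 13.19 ± 0.12 in controls and 13.36 ± 0.06 in susceptible mice (SD, n = 3 each), near the top of the signal range. The list's camera adjusted p was 0.0569 without control 1 and 0.05003 without susceptible 3. With each array's choroid plexus content as a covariate limma called 0 genes between susceptible and control mice, and the differences became 0.44 for A2m, 0.24 for Notch2, 0.24 for Wfikkn2, 0.23 for Ccnd3, 0.39 for Adh1, 0.39 for Tnrc18 and 0.31 for Fkbp5, with adjusted p-values of 0.246 to 0.363. With the same covariate and its preset correlation camera called the glucocorticoid-induced genes (adjusted p = 0.00265) and chromatin regulators (adjusted p = 0.00284) in that comparison, although without the covariate both calls ended with an estimated correlation (adjusted p = 0.652). The adjusted p with the covariate was 0.150 for the microRNA machinery, 0.227 for oligodendrocyte markers, 0.303 for microglia markers and 0.430 for olfactory and vomeronasal receptors.

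Glucocorticoid-induced genes rose in susceptible mice, with 14 of 15 higher and a median of 0.15 (camera adjusted p = 0.0232; adjusted p = 0.652 with an estimated correlation). Fkbp5 and Ddit4 (0.26, SE 0.051) were the 2 members called over all genes, and 9 were called adjusted over the list alone, and Plin4 had a difference of 0.52 (SE 0.15). Without susceptible 2 the list's adjusted p was 0.0717. The microRNA machinery rose too, with 13 of 15 higher and a median of 0.12 (camera adjusted p = 0.0441; adjusted p = 0.652 with an estimated correlation). Tnrc6c (0.27, SE 0.053) was the 1 member called over all genes, against 7 adjusted over the list alone, and Ago1 (0.14, SE 0.039) and Mov10 (0.26, SE 0.072) were not called over all genes. That list's adjusted p was 0.0854 without control 1, 0.0833 without susceptible 1 and 0.0526 without susceptible 3. Chromatin regulators rose, with 13 of 14 higher and a median of 0.13 (camera adjusted p = 0.0179; adjusted p = 0.652 with an estimated correlation). Dnmt3a (0.26, SE 0.053) and Kmt2a (0.21, SE 0.042) were the 2 called over all genes, against 6 adjusted over the list alone, and Ehmt1 had a difference of 0.32 (SE 0.072). Without susceptible 1 the adjusted p was 0.0569, and the list's median stood at percentile 86.05 of random lists matched on signal and gene length. With arrays shifted to one median the medians were 0.09 for glucocorticoid-induced genes, 0.06 for the microRNA machinery and 0.07 for chromatin regulators, and with quantile normalisation they were 0.13, 0.07 and 0.05.

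Oligodendrocyte and myelin markers fell in susceptible mice, with 6 of 6 lower and a median of -0.24 (camera adjusted p = 0.0112; adjusted p = 0.652 with an estimated correlation). Differences were -0.57 (SE 0.18) for Opalin, -0.39 (SE 0.089) for Aspa and -0.22 (SE 0.081) for the transcription factor Nkx6-2, with 0 members called over all genes and 5 adjusted over the list alone. Microglia and macrophage markers fell, with 8 of 8 lower and a median of -0.16 (camera adjusted p = 0.0165; adjusted p = 0.652 with an estimated correlation). The lipid receptor Trem2 had a difference of -0.31 (SE 0.12), Fcer1g -0.30 (SE 0.13) and C1qc -0.19 (SE 0.071), and limma called 0 members, over all genes or over the list alone. Without control 1 or susceptible 1 the adjusted p of the microglial list was 0.0569 or 0.0628. Olfactory and vomeronasal receptor genes rose, with 447 of 588 higher and a median of 0.10 (camera adjusted p = 0.0112; adjusted p = 0.718 with an estimated correlation), and 7 higher and 1 lower were called over all genes and 0 adjusted over the list alone. Without susceptible 3, whose list average lay 0.15 above the control mean against 0.03 and 0.08 in the other susceptible arrays, the adjusted p was 0.0526 and the median 0.07. With arrays shifted to one median the receptors' median was 0.04, and with quantile normalisation that of microglia markers was -0.25. All 7 lists called in susceptible mice had an exact permutation p of 0.100, the smallest that 3 arrays against 3 can give, so that test could not call any.

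**Figure D3:**
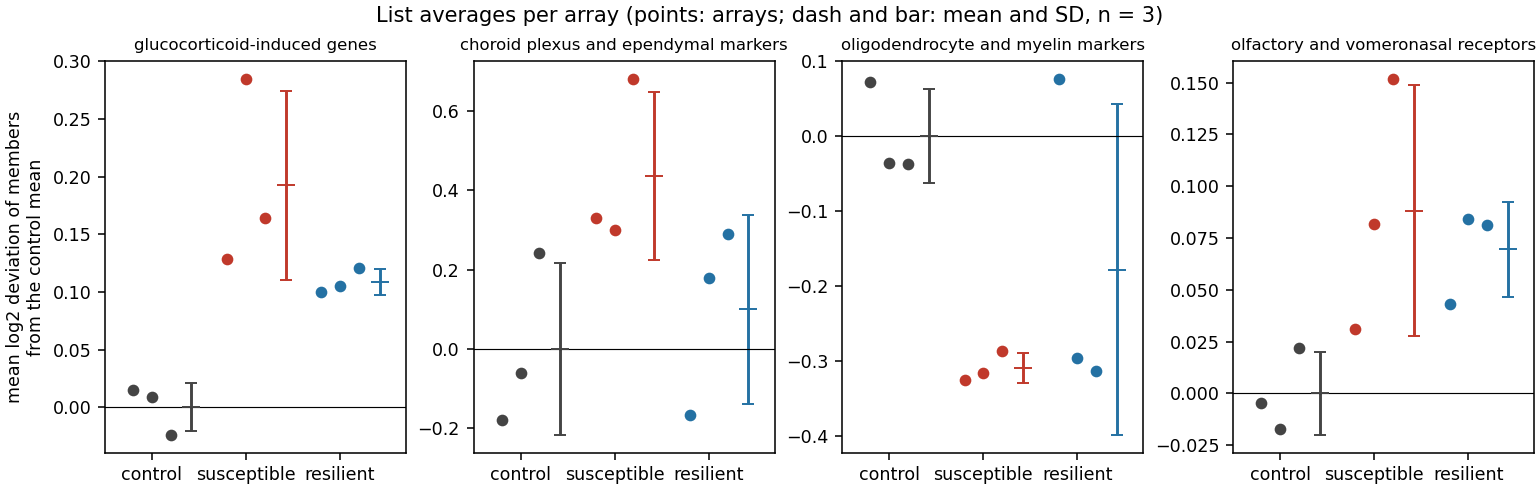
Average log2 deviation of the members of 4 gene lists from the control mean on each array, by group, with points for arrays and a dash and bar for the mean and SD of 3 arrays; each panel has its own axis. Glucocorticoid-induced genes lay between 0.10 and 0.28 on the 6 defeated arrays, choroid plexus markers between -0.17 and 0.29 on the resilient and between 0.30 and 0.68 on the susceptible arrays, and oligodendrocyte markers of resilient 1 at 0.08.

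Resilient mice set against controls gave 0 genes called by limma, with a smallest adjusted p of 0.179, while 2077 genes had an unadjusted p under 0.05, 1332 higher and 745 lower. Because of the table's selection, that count holds chance differences and is not a number of changed genes. Fkbp5 was 0.34 higher (SE 0.067), or 1.26-fold, with an adjusted limma p of 0.00789 over the genes fixed in advance and 0.0275 with the allowance for selection, on all 3 resilient arrays. Its exact permutation p was 0.100, the smallest possible for 3 arrays against 3. Dicer1 was 0.23 higher (SE 0.065), with adjusted p-values of 0.0369 and 0.129 in the same limma tests. The genes of lowest p included Tnrc18 (0.30, SE 0.041), Pggt1b, a subunit of a protein prenyltransferase (0.36, SE 0.051), Klhl18 (0.24), Taz (0.26), Rhbdl3 (0.23), Iglon5 (0.21), Atp11a (0.33), Casp8ap2 (0.20), Jade1 (0.21) and Ifi30 (0.27), none of which passed over all genes. On the lower side they included Arhgap5 (-0.27, SE 0.043), Fam163a (-0.23), Rbm11 (-0.21), Hacd2 (-0.23), Btnl5-ps (-0.62), the small GTPase Cdc42 (-0.15), Selenok (-0.36), Ube2l6 (-0.24) and the ESCRT gene Tsg101 (-0.20), with limma adjusted p-values from 0.179. Second entries, at mean log2 signals of 10.25 for Tsg101, 9.96 for Hacd2 and 4.71 for Btnl5-ps, had differences of 0.04, 0.03 and -0.04. Without susceptible 1, which enters the shared spread, 3 genes were called in this comparison.

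The lists that moved in resilient mice overlapped those of susceptible mice. Chromatin regulators rose, with 14 of 14 higher and a median of 0.12 (camera adjusted p = 0.00998; adjusted p = 0.652 with an estimated correlation), including Dnmt3a (0.25, SE 0.053), Kmt2a (0.18, SE 0.042) and Ehmt1 (0.21, SE 0.072), with 0 members called over all genes and 2 adjusted over the list alone by limma. The microRNA machinery rose, with 13 of 15 higher and a median of 0.09 (camera adjusted p = 0.0241; adjusted p = 0.652 with an estimated correlation). Tnrc6c (0.21, SE 0.053), Dicer1 (0.23, SE 0.065) and Mov10 (0.25, SE 0.072) had the lowest p, with 0 called over all genes and 4 adjusted over the list alone. Without control 1 or resilient 3 the adjusted p of that list was 0.0743 or 0.0524. Circadian clock genes rose, with 12 of 13 higher and a median of 0.10 (camera adjusted p = 0.0441; adjusted p = 0.652 with an estimated correlation). The clock repressor Nr1d2 (0.20, SE 0.041), the clock output gene Dbp (0.26, SE 0.064) and Per3 (0.19, SE 0.050) led them, with 0 called over all genes and 4 adjusted over the list alone, and the 1 lower member was Arntl (-0.14). The clock list's adjusted p was 0.0854, 0.0796, 0.0526 and 0.0682 without control 1, control 4, susceptible 3 and resilient 3. Its median was 0.17 without resilient 1, and as deposited stood at percentile 93.5 of random lists matched on signal and gene length. With arrays shifted to one median the medians were 0.09 for chromatin regulators, 0.06 for the microRNA machinery and 0.07 for clock genes, and with quantile normalisation they were 0.06, 0.07 and 0.08.

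Oligodendrocyte and myelin markers fell in resilient mice, with 6 of 6 lower and a median of -0.19 (camera adjusted p = 0.0441; adjusted p = 0.652 with an estimated correlation). Aspa was at -0.19 (SE 0.089) and Fa2h at -0.21 (SE 0.10), with 0 called over all genes or over the list alone by limma, and the list average of resilient 1 was at the control level. Without control 1, any susceptible array, resilient 2 or resilient 3 the list's adjusted p lay between 0.0526 and 0.274. Its median was -0.29 without resilient 1 and -0.10 without resilient 2. Histone genes fell, with 12 of 17 lower and a median of -0.06 (camera adjusted p = 0.0252; adjusted p = 0.652 with an estimated correlation), H4c6 at -0.37 (SE 0.11) and H1f1 at -0.15 (SE 0.053) but H2ac4 at 0.30 (SE 0.11), and limma called 0 members over all genes or over the list alone. The histone list's adjusted p was 0.0502 without control 4 and 0.0682 without resilient 3, and its median stood at percentile 21.6 of random lists matched on signal and gene length. Olfactory and vomeronasal receptor genes rose, with 454 of 588 higher and a median of 0.07 (camera adjusted p = 0.00998; adjusted p = 0.718 with an estimated correlation), 0 of them called over all genes or over the list alone by limma. With choroid plexus content as a covariate the camera adjusted p was 0.0587 for the microRNA machinery, 0.113 for oligodendrocyte markers and 0.0803 for circadian clock genes. The median with arrays shifted to one median was -0.10 for histone genes and 0.04 for the receptors. The exact permutation p was 0.400 for oligodendrocyte markers and 0.100, the smallest possible, for the other 5 lists called in resilient mice.

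The differences of susceptible and of resilient mice from control ran in the same direction for most genes. Of the 235 genes called in susceptible mice, 234 had the same sign in resilient mice, and in 230 the resilient difference was smaller, with a median ratio of 0.634. Choosing genes by their susceptible difference favours a smaller resilient one. Across all 9803 genes, 83.4% had the same sign, the correlation of the differences was r = 0.755 and their covariance was 0.0141. Unchanged groups simulated against shared controls gave r = 0.501 and a covariance of 0.00273, and simulated groups that had also passed the table's selection gave r = 0.498, a covariance of 0.00545 and the same sign in 66.7%. Only 3 controls were measured, and they were not split to give each defeated group its own controls. Part of the excess may therefore come from the shared controls. Genes are not independent replicates in this correlation.

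Susceptible and resilient mice set against each other gave 0 genes called by limma, with 1158 at an unadjusted p under 0.05, 648 higher and 510 lower. Such a count holds chance differences from the larger number of symbols behind the selected table, so it does not show that these genes differed. The smallest adjusted p was 0.346, that of Syt10, a synaptotagmin of secretory vesicles, at 10.33 ± 0.02 in susceptible and 10.65 ± 0.07 in resilient mice (SD, n = 3 each, limma difference -0.32). The other genes of lowest p on the lower side were the chemokine gene Ccl28 (-0.38), the potassium channel gene Kcnk2 (-0.42), the netrin receptor Unc5d (-0.23), Hs6st2 (-0.29), the cadherin Cdh6 (-0.37), Tekt5 (-0.57), the GABA-A receptor subunit Gabrd (-0.30), Olfm3 (-0.30) and Gsg1l (-0.36). On the higher side they included Nhsl1 (0.20), Ralgds (0.19), Tmem18 (0.24), Zfp235 (0.15), A2m (0.65), Prdm16 (0.24), Tmem53 (0.29), Pag1 (0.14) and Rflnb (0.13), all with a limma adjusted p of 0.411. A second entry of Prdm16, at a mean log2 signal of 5.53, differed in the opposite direction (-0.17), and second entries of Nhsl1 and Unc5d differed by 0.01 and -0.06. Fkbp5 differed by 0.09 (SE 0.067) between the defeated groups, with an adjusted limma p of 0.482 and an exact permutation p of 0.400. Without susceptible 1, 6 genes were called in this comparison.

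Choroid plexus and ependymal markers were higher in susceptible than in resilient mice. All 13 members were higher, with a median of 0.34 (camera adjusted p = 0.00171; adjusted p = 0.652 with an estimated correlation). Folr1 differed by 0.45 (SE 0.20), Clic6 by 0.34 (SE 0.14), Tmem212 by 0.34 (SE 0.12) and Ttr by 0.14. Glucocorticoid-induced genes were higher in susceptible mice too, with 14 of 15 higher and a median of 0.09 (camera adjusted p = 0.0392; adjusted p = 0.652 with an estimated correlation). The members of lowest p were the siderophore-binding lipocalin Lcn2 (0.13, SE 0.048), Ddit4 (0.13, SE 0.051) and the cell cycle inhibitor Cdkn1a (0.13, SE 0.051). That list's adjusted p was 0.357 without susceptible 2, with a median of 0.05, 0.0524 without control 1, 0.0535 without resilient 2 and 0.0682 without resilient 3. The choroid plexus call kept an adjusted p under 0.05 without any single array, but its median was 0.24 without susceptible 3 and 0.19 without resilient 1, and the adjusted p was 0.168 without both.

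Of the 26 genes on the CRH, steroid and stress peptide list, 5 were in the selected table. Crh, Crhr1, Nr3c1 and Nr3c2 were not among them. Only 2 of the 5 had a control signal above the 95th percentile of olfactory and vomeronasal receptors. All 5 were lower in susceptible than in resilient mice, with a median of -0.10. The camera adjusted p was 0.0391, and 0.652 with an estimated correlation. The 5 genes were the peptide gene Ucn2 (-0.13, SE 0.053), Oxt, which encodes oxytocin (-0.12, SE 0.062), the vasopressin receptor Avpr1b (-0.10, SE 0.047), Avp, which encodes vasopressin, and Adcyap1r1. The adjusted p was 0.0687 to 0.0784 without susceptible 2, susceptible 3, resilient 2 or resilient 3, and the median -0.06 without susceptible 3. Of the 20 thalamic and hypothalamic markers, 5 were in the table. All 5 were lower, with a median of -0.12 (camera adjusted p = 0.0290, and 0.652 with an estimated correlation). They were led by the vesicular glutamate transporter Slc17a6 (-0.32, SE 0.14) and the transcription factor Sim1 (-0.12, SE 0.056), and they share Oxt and Avp with the preceding list. Without susceptible 3 or resilient 2 that adjusted p was 0.121 or 0.0588, and the median was -0.07 without susceptible 3. With choroid plexus content as a covariate the adjusted p was 0.133 for the stress peptide list and 0.490 for the thalamic and hypothalamic list. limma called 0 members of these 4 lists, over all genes or adjusted over the list alone. The exact permutation p was 0.100, the smallest possible, for 3 of these lists and higher for the stress peptide list, with an adjusted p of 0.457 for all 4.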

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

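The tests of how the choroid plexus markers vary together within groups and of leaving out 2 arrays together were chosen only after the result was seen, and the test without susceptible 3 was planned before it. The results given first drew attention because camera, which tests a list against the other genes, called a difference between susceptible and resilient mice.

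Choroid plexus and ependymal markers had a median difference of 0.34 (13 of 13 members higher in susceptible mice), glucocorticoid-induced genes 0.092 (14 of 15 higher), the CRH, steroid and stress peptide genes -0.10 (5 of 5 lower) and thalamic and hypothalamic markers -0.12 (5 of 5 lower). Their camera adjusted p-values were 0.00171, 0.0392, 0.0391 and 0.0290, and fry, which does not compare a list with other genes, gave 0.221, 0.174, 0.127 and 0.250. With an estimated correlation camera called none of the 4 (adjusted p = 0.652 each). Among random lists matched on signal and gene length the choroid plexus median stood above all 10000, the glucocorticoid median at percentile 99.4, and the stress peptide and thalamic medians at percentiles 2.03 and 0.85. Of the 5 stress peptide genes 2 had a control signal above the 95th percentile of olfactory and vomeronasal receptors, which serve mainly outside the brain, and the count was 2 of 5 for the thalamic and hypothalamic genes as well.

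Choroid plexus markers averaged -0.18, -0.06 and 0.24 against the control mean on the control arrays, 0.33, 0.30 and 0.68 on the susceptible and -0.17, 0.18 and 0.29 on the resilient arrays. Camera at its preset correlation of 0.01 cannot decide whether susceptible 3 alone was the cause. The members correlated far more than that between arrays of one group (0.627, given below). Without susceptible 3 the test's adjusted p for the difference between susceptible and resilient mice was 0.0126. The median kept its direction but was 0.24, against 0.34 with all arrays, and it was 0.19 without resilient 1. Without both arrays the adjusted p was 0.168. With an estimated correlation there was no call even with all arrays (adjusted p = 0.652). A candidate explanation is the amount of choroid plexus tissue taken with each amygdala. The members also varied as a unit between arrays of one group, with a mean pairwise correlation of 0.627 of their deviations from the group mean. A change of expression shared by the members could give such a correlation as well, and no other list was set beside it. The correlation therefore cannot tell these explanations apart. Of the 13 members 2 are also on the potassium channel list, and the abundant Ttr, at 13.36 in susceptible and 13.22 in resilient mice, lay too near the top of the signal range to show how much tissue would be needed. A difference in choroid plexus RNA between susceptible and resilient mice themselves was not tested and stays open.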

How the results depend on the processing

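The allowance for selection, choroid plexus content as a covariate and the removal of susceptible 3 with resilient 1 were tests chosen only after the results were seen. For each setting the number of genes called is given first for defeated minus control (126 as reported) and then for susceptible minus control (235 as reported). It was 75 and 99 with every table entry tested, 439 and 552 among genes above the median signal, 306 and 382 among genes above the 95th percentile of olfactory and vomeronasal receptors, 164 and 1497 with arrays shifted to one median, 3 and 12 with quantile normalisation, 236 and 395 with trend and robust, 10 and 20 without moderation, 2084 and 3443 with array weights, 40 and 2 with only the groups compared, 8 and 30 at unadjusted p under 0.05 with 1.5-fold, 0 and 1 with the allowance for selection, 0 and 0 with choroid plexus content as a covariate, and 214 and 0 without susceptible 3 and resilient 1. With 1 array left out the counts ran from 0 to 1333 and from 0 to 1930. Resilient minus control and susceptible minus resilient gave 0 except 5 and 7 at unadjusted p under 0.05 with 1.5-fold, and 0 to 3 and 0 to 6 with 1 array left out. Fewer genes tested explain part of the rise under the filters, and the allowance acts by its construction. For the other moves the cause was not tested.

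With the replicate number as a block (a replicate block in limma) the counts were 0 and 0. Deviations of same-numbered arrays correlated between -0.100 and 0.215, and those of other pairs between -0.290 and 0.340. These values do not show a pairing by number and cannot exclude one. Control 4 had no same-numbered partner, so with the block it carried no weight in the differences. The block changed 4 of the 24 list calls.

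The correlation between the differences of susceptible and resilient mice, 0.755 as reported, was 0.716 among genes above the median signal, 0.717 above the receptor percentile, 0.734 with quantile normalisation, 0.709 with the covariate, and 0.657 to 0.812 with 1 array left out. The cause was not tested.

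No called list changed direction, and neither did any called gene among those named, by the entries kept. The counts did, from 99 of 126 and 181 of 235 higher as reported to 42 of 164 and 231 of 1497 with arrays shifted to one median and 1 of 3 and 5 of 12 with quantile normalisation. Medians over all table entries were 7.11 to 7.13 on control and 7.15 to 7.19 on defeated arrays. A shift to one median therefore lowers defeated values against controls by construction. Both settings rescaled only the selected table, and for quantile normalisation the cause was not tested. Across all alternatives list calls held 337 times and were lost 154 times, and named genes kept their side of the threshold 2799 times, lost it 668 times and gained it 62 times. An estimated correlation ended 24 of 24 list calls, fry 15, quantile normalisation 11 and the covariate 14, while fry also passed 15 list comparisons that camera did not call. In defeated mice the fry adjusted p was 0.138 for oligodendrocyte markers, 0.162 for microglia markers, 0.310 for ribosomal proteins and 0.111 for the receptors. It was 0.0398 there for glucocorticoid-induced genes, 0.0224 for the microRNA machinery and 0.00836 for chromatin regulators. For choroid plexus markers in susceptible mice it was 0.146. The table's selection favours a pass by fry, and no allowance was made for it. No called list changed the sign of its median under either scaling, but sizes moved. In defeated mice the median of chromatin regulators, 0.13 as reported, was 0.05 with quantile normalisation, and with arrays shifted to one median that of the microRNA machinery went from 0.11 to 0.06, glucocorticoid-induced genes from 0.14 to 0.09, ribosomal proteins from -0.07 to -0.12 and the receptors from 0.09 to 0.04. The difference of Fkbp5 between defeated and control mice lay between 0.30 and 0.43 under 23 alternatives, with an adjusted p over all genes from 0.0150 to 0.150, and the call held in 10 of the 23. The second deposited value table and the microRNA seed test were not run. Signal over background limits what the arrays show of genes near the level of the olfactory and vomeronasal receptors, whose 95th percentile was 6.12, and 3 arrays per group limit small differences.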

Other observations

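The tests of striatal and cholinergic genes, of gene length, of the part of the Fkbp5 difference left after subtracting genes of like signal and of why the Fkbp5 call ended were chosen only after the results were seen. Among the largest differences between susceptible and resilient mice, 5 genes of striatal or cholinergic neurons are given as values only. They were picked after their values were seen, no list of cholinergic genes was fixed in advance, and limma called none of them (adjusted p = 0.411 each). The sodium channel subunit gene Scn4b was at 7.74 ± 0.65 in susceptible, 9.01 ± 0.89 in resilient and 8.78 ± 0.35 in control mice (SD, n = 3 each). The choline transporter Slc5a7 differed by -0.83 between susceptible and resilient mice, the vesicular acetylcholine transporter Slc18a3 by -0.79, the orphan receptor Gpr6 by -0.65 and the dopamine receptor Drd2 by -0.54. The list of central amygdala and striatal-type markers had 5 of 6 members lower in susceptible mice, with a median of -0.28 (camera adjusted p = 0.0733). Resilient 1 carried the resilient side, at 0.39 above the control mean against -0.04 on both other resilient arrays, and the susceptible arrays were at 0.01, -0.23 and -0.20. Without resilient 1 the median was -0.16 (adjusted p = 0.331), and without resilient 2 or resilient 3 the adjusted p was 0.0225 or 0.0395.

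Gene lists without a call are given with their lowest camera adjusted p over the 4 comparisons. Immediate early genes had 0.0601 (susceptible minus resilient, 6 of 6 higher, median 0.10), interferon-stimulated genes 0.0601 (resilient minus control, 5 of 6 lower, median -0.12), reported miR-15/16 family targets 0.0540 (susceptible minus resilient, 8 of 10 higher), mitochondrial respiratory chain genes 0.0568 and blood cell markers 0.0608. Zinc finger proteins had 0.0770, small nucleolar RNA genes 0.109, potassium channels 0.129, basolateral amygdala and cortical excitatory markers 0.193, glutamate receptors 0.193, synaptic plasticity genes 0.206 and the dopamine and opioid systems 0.222. Inflammatory genes and pan-neuronal markers had 0.379, steroid receptor chaperones and endothelial and mural markers 0.457, the 149 microRNA genes 0.504, astrocyte markers 0.821 and protocadherins 0.940. By fry, which does not compare a list with other genes, the adjusted p was under 0.05 against control in all 3 comparisons for interferon-stimulated genes (0.00837 to 0.0105), synaptic plasticity genes (0.01002 to 0.0186) and zinc finger proteins (0.0140 to 0.0313). It was 0.0425 in defeated and 0.0291 in resilient mice for glutamate receptors, 0.0203 in susceptible mice and 0.0291 in susceptible minus resilient for blood cell markers, 0.0241 in susceptible minus resilient for immediate early genes and 0.0425 in defeated mice for circadian clock genes. With an estimated correlation camera called none of these lists (adjusted p = 0.652 to 0.690). Members were in the table because the groups differed, which favours a pass by fry, and no allowance was made for it. Of the 20 interferon-stimulated genes 6 were in the table, and 2 of those had a control signal above the 95th percentile of the receptors. In lists too small to test, differences between defeated and control mice were -0.18 for the GABA-A receptor subunit Gabrb2, 0.15 for the endocannabinoid enzyme Dagla, 0.11 for Pdgfra and 0.23 for Cspg4 of oligodendrocyte precursors, -0.26 for the hippocampal marker C1ql2 and 0.03 for the serotonin receptor Htr2c.

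Differences between defeated and control mice went with gene length. Among 9405 genes with a length, the 1881 shortest had a median of -0.02 with 46.3% higher, and the 1881 longest a median of 0.09 with 75.2% higher (Spearman's rho 0.245 across genes, which are not independent replicates). Against random lists matched on signal and length, the defeated minus control median of glucocorticoid-induced genes stood at percentile 99.9, that of the microRNA machinery at 98.3, chromatin regulators at 95.1 and microglia markers at 0.07, and oligodendrocyte markers stood below all 10000. Ribosomal proteins in defeated mice (percentile 20.2), chromatin regulators in susceptible mice (86.05, with a median of 0.13 against 0.10 for the matched lists) and circadian clock genes (93.5) and histone genes (21.6) in resilient mice stood little apart from genes of like signal and length.

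Olfactory and vomeronasal receptor genes, as a class with little expression in brain, were higher in defeated mice by a median of 0.09. A shift shared by all genes of low signal is argued against, because other genes matched on signal had a mean median of -0.047 over 10000 random lists, none of which reached the receptors' median. The receptors averaged 0.03, 0.08 and 0.15 above control on the susceptible and 0.04, 0.08 and 0.08 on the resilient arrays. With choroid plexus content as a covariate the list's adjusted p was 0.113, so a link of the receptor values to sample composition stays open, and no biological explanation was tested.

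Fkbp5 in defeated mice was higher by 0.38 (SE 0.058). Choroid plexus content as a covariate left 0.31 (SE 0.059, limma adjusted p = 0.150 over all genes), so it does not account for most of the difference. The call over all genes ended with the p-values of the other genes, since the unadjusted p of Fkbp5 with the covariate, 0.000574, would have had an adjusted p of 0.0485 among the other genes as they stood without it, where 175 genes rather than 58 had an unadjusted p under 0.001. The 500 genes nearest in signal had a median difference of 0.10, which lay between the bounds set beforehand as shares of the Fkbp5 difference, so a part played by such a shift cannot be told apart from none. As the whole cause the shift is argued against, since the remaining 0.28 was 4.92 standard errors and 3 of the 500 genes reached the Fkbp5 difference. A response of Fkbp5 to defeat itself may account for the rest, as a hypothesis, and whether more Fkbp5 RNA was made or more of it was bound to Ago2 was not tested.

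Splits of the arrays into other groups were refitted on the same genes, which had been selected with the real groups, so the splits favour the real one and do not show whether chance can be excluded. The real split of defeated and control mice gave 126 genes, and 1 of the 84 splits gave as many, with 78 the highest of the others. The 10 splits of susceptible and control arrays are too few for a share under 0.05; the real one gave 235, as many in 1 split, and the highest other 0. For resilient and control arrays and for susceptible and resilient arrays 10 splits are too few as well, and the real split and the highest other both gave 0, with 10 of 10 splits as high.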
